A study of Bacillus subtilis with 2 samples.

How the data were processed

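The series held 2 two-colour microarrays of Bacillus subtilis 168, a Gram-positive soil bacterium. Each array compared cDNA of a clpX mutant with cDNA of a clpX spx double mutant. ClpX is the ATPase subunit of the ClpXP protease, which degrades the transcriptional regulator Spx, so Spx accumulates in a clpX mutant and is absent from the double mutant. Per the labels' protocols, cells were grown in 50 ml LB at 37 °C and 300 rpm and harvested in exponential growth at an OD of 0.6. Total RNA was treated with DNase, and cDNA primed with random hexamers was labelled indirectly with the Alexa 555 and Alexa 647 dyes. The series' design text describes dye-swapped labelling of the same RNA preparations. The 2 arrays were therefore treated as technical repeats of 1 preparation per strain, and no p-value across biological replicates was computed. The number of arrays limits the precision.

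The labels disagree in 2 places. They assign Alexa 647 to the clpX strain on both arrays, although the second array is titled a dye swap. If the dye labels hold, a dye effect would follow the strain and would not cancel in the mean of the arrays. They also name steps of 15 min at 48 °C and 15 min at 53 °C as the source of channel 2 on both arrays, whereas the growth protocol gives only 37 °C. Channel 2 holds the clpX spx strain on the first array and the clpX strain on the second, so a treatment of channel 2 would not follow the strain.

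The value table the authors deposited holds 1 number per spot and array, identified by a spot number from 1 to 8704. Its unit is not given in the sources used here, and nor are the scanner, the background correction or the normalization. In both columns every entry with a decimal point was below 1 in size and every entry without one was 1000 or more in size, with 0 entries between. Entries without a decimal point were therefore divided by 1000. Read in this way, the deposited columns are linear ratios with medians of 0.974 and 0.966. Entries of 0 (15 and 20 spots on arrays 1 and 2), negative entries (108 and 96) and a placeholder value above 1000 (21 and 10) were left out. That left 8560 and 8578 usable spots.

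Spot ratios 132 rows apart within each block of 272 rows agreed best (mean r = 0.855 over both arrays, against 0.279 for the next best distance), so these spots were taken as pairs of the same probe. This gave 4224 features in 32 blocks, with 256 rows outside pairs not used. The block size, the pair distance and the placeholder limit were found from the values. The log2 ratios of the 2 spots were averaged, and 4191 features had usable values on both arrays. Spots of a pair correlated with r = 0.920 on array 1 and 0.922 on array 2. The rows carry no gene names, so no feature of the value table was named. Ratios are without intensities, so signal over background is not known.

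The second file the authors deposited lists 378 genes by identifier and symbol, each with 1 combined ratio. Per the file headers this is the ratio of clpX over clpX spx, so values above 1 mean higher transcript levels in the clpX strain. Only ratios of at least 2.012 or at most 0.496 are listed. The way the ratio was made is not given in the sources used here and was searched for in the value table, by trying many formulas and orientations of the arrays on these data. In the formula kept, the geometric mean of the paired spots was taken on each array, array 2 was inverted, and the arithmetic mean of the 2 arrays was formed. This gave a feature within 0.0005 of the table's value for 372 of 378 genes, and for 112 of the 114 genes above 3. With array 1 inverted instead, 105 and 6 values were found, and 98 and 6 were found after every table value had been moved by 0.0137. The direction of both arrays was taken from this match. The first column then is clpX over clpX spx and the second its inverse, although both titles name the ratio in the same order. Before the data were examined, the direction had been planned from the titles for both arrays, with the second array turned as the alternative. The 2 were exchanged after seeing the match and the correlation of the columns as deposited (Pearson r = -0.447).

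For the features, log2 ratios were turned to clpX over clpX spx and averaged over the arrays. The size rule counted features with a mean log2 ratio of at least 1 in size (2-fold) and the same sign on both arrays. In simulated data with 200 changed features and noise in the mean drawn from the real differences between the arrays, the rule recovered 91% of features changed by 1.5 and 99% of those changed by 2.0 on the log2 scale. It also took in 182 of 3991 unchanged features (4.56%). The size of the noise in the mean was assumed. The simulation held no variation between cultures and no dye effect that follows the strain, so 4.56% is not the error rate of this design.

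The plan had assumed gene names in the value table, and named genes and list medians were taken from the authors' deposited table instead. Because that table holds only ratios past 2-fold, list medians are over listed genes and unlisted genes have no value here. The 20 gene lists, written before the data were examined, were compared with the authors' deposited table. They cover thiol redox and bacillithiol synthesis, sulfur and methionine metabolism, heat shock, SigB, PerR and quinone stress, anaerobic growth, ComA and ComK competence genes, motility, ribosomal proteins, nucleotides, amino acids, iron, biofilm and cannibalism, SOS and prophage genes, SigW and the citric acid cycle with respiration. List sizes count members named in the table or among 4237 protein-coding genes of the ASM904v1 reference, which matched 323 of the 378 table names (85.4%). Renamed genes may be counted under both names. A written name that the reference does not hold counts only if the table lists it, which raises the share of listed genes. This applies most to the iron list (14 of 31 written names) and SigW (22 of 30). Each list's number of listed genes was set against 10000 random lists of the same size, and the median log2 ratio of its listed genes, where at least 3 were listed, against 10000 random sets of listed genes. Random lists ignore operons, so each list was also shifted along the gene order in all possible steps, using the members with a known order. These percentages describe this pair of RNA preparations. Random lists could not be matched on expression because no intensities were used here. Named genes are the 12 highest and the 12 lowest ratios, all listed members of the thiol redox and bacillithiol lists, and the 2 highest and 2 lowest of each other list. The rule's further condition, the same sign on both arrays, was not applied to single genes, because features were not named by their values. As a set, the 269 features that alone matched a table value lay on the same side of 1 on both arrays, in a table that holds only ratios past 2-fold.

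The planned check of the spx transcript was not possible: neither spx nor clpX is named in the table used here. Genome coordinates are not given, since no build is named for the array. Alternatives changed the size threshold, the combination of spots and arrays, the centring and the direction of array 2. Another used limma over both arrays as technical repeats. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.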

Results

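Transcript levels of a Bacillus subtilis clpX mutant and a clpX spx double mutant were compared on 2 two-colour arrays. The comparison asks which transcripts depend on the regulator Spx when it is not degraded by ClpXP. All samples were of 1 RNA preparation per strain hybridised 2 times. The spread between the arrays is therefore technical, and variation between cultures cannot be told apart from the difference between the strains. Neither spx nor clpX is named in the table used here, and the deletions were not checked on the transcript level.

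Across the array, 4191 features (probe pairs without gene names) were measured on both arrays. Of these, 357 (8.52%) were at least 2-fold higher in clpX and 255 (6.08%) at least 2-fold lower, by the mean of the 2 arrays with the same sign on both. Array 2 alone gave 552 higher and 324 lower features past 2-fold, and array 1 alone gave 515 and 385. The highest feature had a mean log2 ratio of 3.93, with 4.65 on array 1 and 3.22 on array 2. The lowest had a mean of -4.56, with -4.13 and -4.98. Of the features past this rule, 188 of the higher and 164 of the lower were past 2-fold on each array by itself. The arrays correlated with Pearson's r = 0.447 and Spearman's rho = 0.278 across features, which are not independent replicates, and 57.2% of features had the same sign. The deviation of an array from the mean of both had an SD of 0.48 on the log2 scale over all features.

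**Figure D1:**
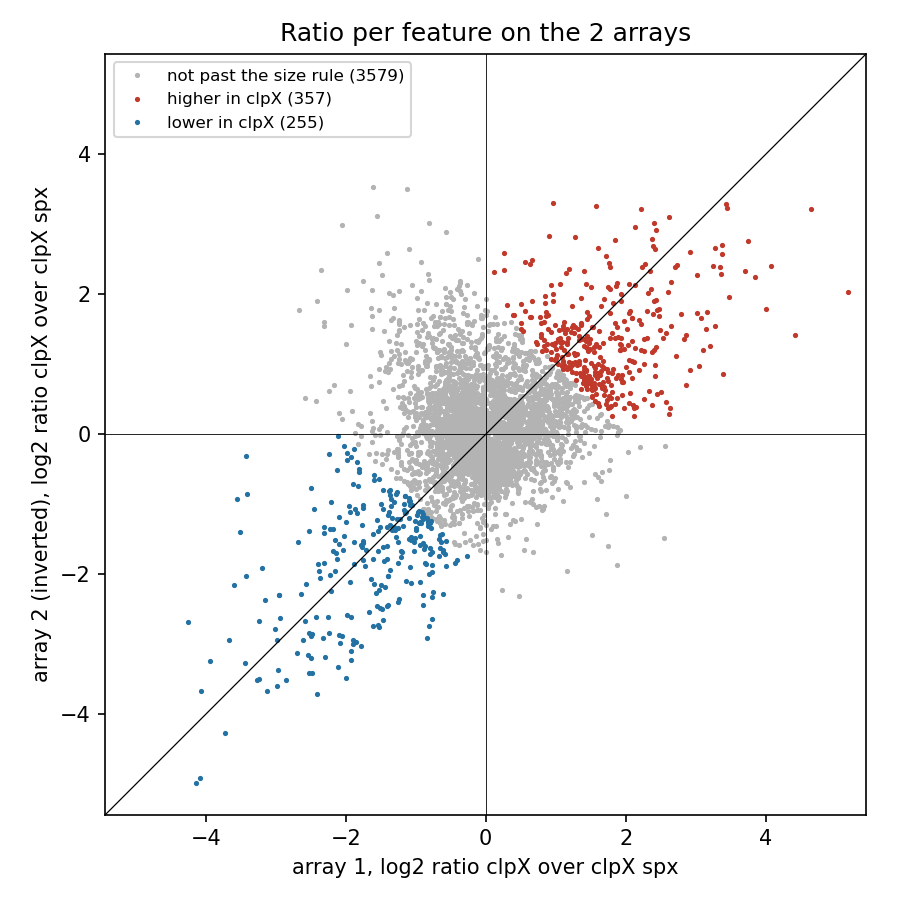
Log2 ratio of clpX over clpX spx per feature on array 1 (x axis) and on array 2 after inversion (y axis), each point being the mean of 2 spots. The 357 red and 255 blue features are at least 2-fold higher and lower in clpX by the mean of both arrays, and the black diagonal marks equal values.

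The authors' deposited table named 378 genes, 201 of them higher in the clpX strain and 177 lower. The median ratio was 3.22 among the higher genes and 0.304 among the lower ones in that table, and 40 genes were at least 5-fold higher and 48 at least 5-fold lower. The highest ratio in the authors' deposited table was 20.1 for yqgE (BG11677), followed by ytkL at 12.3, ywrO at 11.0, sodF at 10.2 and ywnF at 10.1. The list went on with tpx, a thiol peroxidase, at 9.77, and nfrA, an NADPH-linked flavin reductase, at 9.55. The genes ypqE (9.06), ytzB (8.45), yoxD (8.19), ylaD (8.03) and ypgR (7.72) completed the 12 highest ratios. By the formula found, these ratios are arithmetic means of the arrays, which lie above the geometric mean where the arrays differ. The highest feature with the same sign on both arrays was at 15.3-fold by its mean log2 ratio, which is a geometric mean. The 20.1 of yqgE is an arithmetic mean by that formula, so the 2 values are unlike measures. If the value of yqgE came from a feature with the same sign on both arrays, the arrays differed for that feature. Features were not named, so this was not checked.

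At the lower end of the authors' deposited table stood hemAT, the haem-containing aerotaxis receptor, with a ratio of 0.0445, and hag, which encodes flagellin, with 0.046. These correspond to 22.5-fold and 21.7-fold lower levels in clpX. The glucose permease gene ptsG (0.0635) and the lactate permease gene lctP (0.0695) came next. They were followed by xkdJ (0.0855) of the PBSX prophage, sunT (0.0955), which encodes the sublancin transporter, and dltD (0.097) of D-alanylation of teichoic acids. The purine permease gene pbuG (0.0975), the PBSX genes xkdK (0.0985) and xtmB (0.1035), the flagellar export gene fliR (0.104) and rplB (0.1045), for ribosomal protein L2, completed the 12 lowest ratios.

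Genes of thiol redox control were higher in clpX. The authors' deposited table named 5 of the 9 list members, all higher: tpx and nfrA as above, trxB (thioredoxin reductase, BG12398) with 5.11, trxA (thioredoxin, BG10348) with 4.34 and ycnD (a flavin reductase) with 3.78. None of 10000 random lists of 9 genes held as many higher genes. For the 7 members with a known gene order, 3 of them higher, shifts of the list along the gene order gave as many in 0.212%. The median log2 ratio of the 5 genes was 2.35, at the 99.2th percentile of random sets of listed genes. The list was written from textbook knowledge of Spx targets, so its direction is not independent of earlier work. The methionine sulfoxide reductase genes msrA and msrB were among the 4 members that the table does not name, and have no value here.

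The list for bacillithiol synthesis and genes of its operons had 10 members and may not hold every such gene. Of these 10, 2 were in the authors' deposited table, both higher: bshB2 with a ratio of 3.10 and bshA with 2.53. As many higher genes were found in 7.90% of random lists. For the 9 members with a known gene order, 1 of them higher, shifts along the gene order gave as many in 26.2%. Among chaperones and proteases, htpG (3.83), lonA (3.51) and clpC (2.01) were higher and none of the 21 list members was listed lower, with 7.94% of random lists holding as many higher genes and 5.29% of shifts of the list along the gene order. The iron list, of Fur-type genes, gave ykuO (5.90), ykuP (4.51) and dhbB (2.08), all higher, out of 14 recognised names of 31 written. As many higher genes were found in 2.48% of random lists. For the 13 members with a known gene order, 2 of them higher, shifts of the list along the gene order gave as many in 9.84%. The quinone and organic peroxide list gave ohrA (2.69), a peroxiredoxin for organic hydroperoxides, and yvaB (2.29), both higher, out of 14 (13.8% of random lists). For its 13 members with a known order, 1 of them higher, shifts gave as many in 37.5%.

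Ribosomal protein genes had the most lower transcripts among the 20 lists, which leave many of the 177 lower genes ungrouped. Of 57 gene names starting with rps, rpl or rpm, the authors' deposited table listed 30 as lower and 1, rpmGB (2.43), as higher. The median ratio of the 31 listed genes was 0.239, or 4.19-fold lower, and their median log2 ratio of -2.07 was below those of all 10000 random sets of listed genes. The lowest were rplB (0.1045) and rplP (0.135), and the second highest ratio was 0.492 for rplT. None of the random lists held as many lower genes, where 2.38 were expected.

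Motility and chemotaxis genes were also lower. Of 58 list members, the authors' deposited table listed 22 as lower and 2 as higher, against 2.42 expected as lower and none of the random lists with as many. The listed genes had a median ratio of 0.323. The lowest were hemAT and hag, followed by fliR. The 2 higher genes were flhP (2.60), a flagellar hook-basal body gene, and lytA (2.22), of the lytic operon.

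PBSX prophage genes were lower as well. The authors' deposited table listed 17 of the 39 members of the SOS and prophage list as lower, all with PBSX-type symbols, and 1 as higher, the excision repair gene uvrB (2.23). The median ratio of the 18 genes was 0.249. The lowest were xkdJ and xkdK, and the highest of the PBSX genes was xkdQ at 0.4865. None of the random lists held as many lower genes.

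Most listed genes of the citric acid cycle and respiration list, and all listed genes of the anaerobic growth list, were lower. Of the 29 members of the citric acid cycle and respiration list, 10 were lower and 1 was higher in the authors' deposited table. The lower genes were 5 of the ATP synthase, with atpD lowest at 0.246, 3 of the cytochrome caa3 oxidase (ctaC, ctaE and ctaF), and the succinate dehydrogenase genes sdhC (0.3445) and sdhB. Of these, ctaC, ctaE, ctaF and sdhB are named here to show what the list held, after their values had been seen. The higher gene was qcrA (2.31), of the menaquinol to cytochrome c reductase, and the next highest ratio was 0.4455 for atpH. Of 24 members of the anaerobic list, 7 were listed, all lower. The lowest were lctP and cydA (0.135), of cytochrome bd, and the highest were ctaB (0.375) and narI (0.458), of nitrate reductase. For both lists, none of the random lists held as many lower genes. Shifts along the gene order, which keep neighbouring genes together, gave as many in 0.118% for the citric acid cycle and respiration list and in 1.20% for the 6 lower genes of the anaerobic list with a known order.

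Of 12 genes of the ComA type, which respond to cell density, 5 were listed as lower in the authors' deposited table. The lowest were rapA (0.2135) and srfAD (0.388) of the surfactin operon, and the highest were srfAC (0.4155) of the same operon and degQ (0.458). As many lower genes were found in 0.03% of random lists and 0.378% of shifts along the gene order. The list did not hold rapG, which shares the symbol rap with rapA and was higher at 2.335. This gene was picked after its value was seen. None of the 29 late competence (ComK type) genes, the 32 SigB general stress genes or the 12 PerR peroxide genes was listed in either direction, where 2.59, 2.85 and 1.07 listed genes were expected.

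The remaining lists gave few genes in the authors' deposited table. The sulfur and cysteine list gave cysP, the sulfate permease gene, at 0.1995, and yxeM at 3.36, out of 36 members. The methionine list gave yoaC (2.87) out of 19. The nucleotide list gave pyrE (4.18) and pyrD (3.20) as higher and pbuG as lower, out of 29. The biofilm and cannibalism list gave the transition state regulator gene abrB (4.34) as higher and epsB (0.4865) as lower, out of 29. The amino acid list gave argC (0.35) out of 26, and the SigW list gave yknY (0.323) out of 22. Each of these numbers was reached by at least 40.9% of the random lists in the same direction. The nucleotide list may not hold every such gene. It did not hold pbuO, which shares the symbol pbu with pbuG and was lower at 0.496. This gene was picked after its value was seen. Medians of the other lists with at least 3 listed genes were also set against random sets of listed genes. The percentiles were 0.06 for prophage, 0.48 for motility, 6.54 for anaerobic growth, 18.7 for citric acid cycle and respiration, 23.9 for ComA. They were 82.4 for nucleotides, 86.3 for chaperones and proteases and 95.1 for iron.

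**Figure D2:**
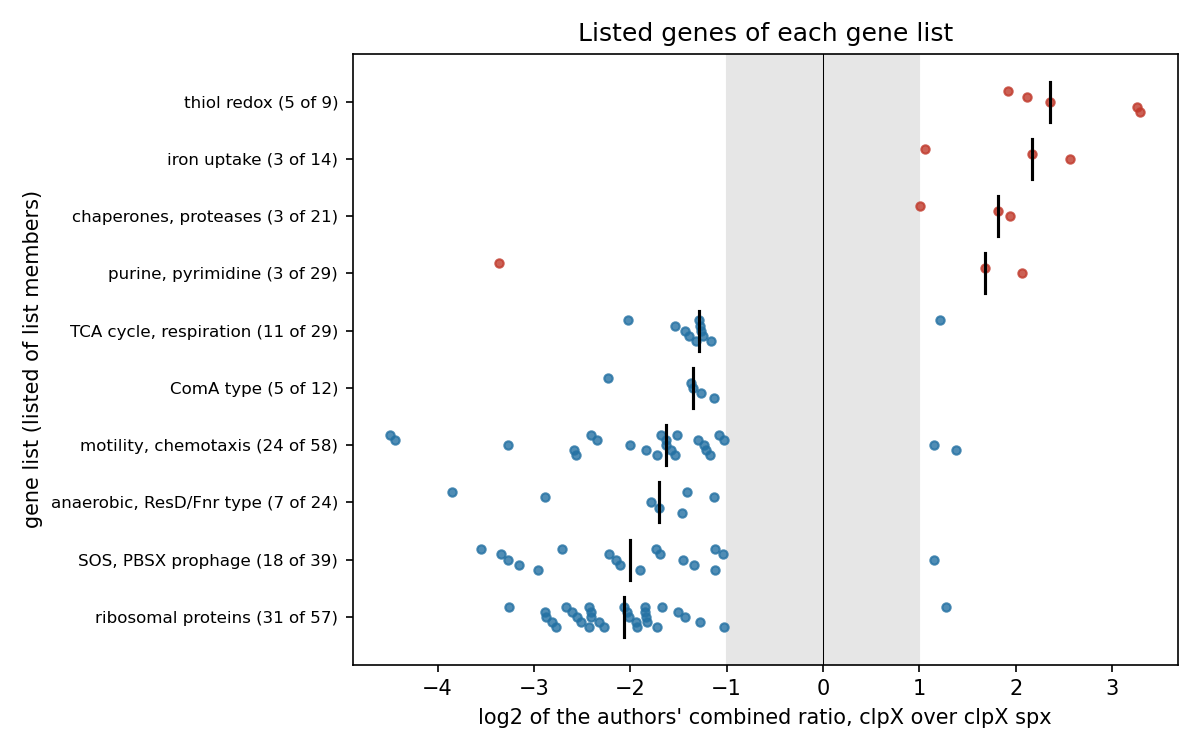
Log2 of the authors' combined ratio of clpX over clpX spx (x axis) for each listed gene (point) of the 10 gene lists with at least 3 listed genes (y axis, with the number listed and the list size). Red and blue mark lists with a median above and below 0, black bars are medians, from 2.35 for thiol redox to -2.07 for ribosomal proteins, and the grey band marks the ratios under 2-fold that the table does not hold.

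The gene-level ratios rest on both arrays but have no error of their own in the table. The authors' deposited table holds only ratios past 2-fold, so agreement of the arrays among its genes gives no unbiased error.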

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

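The arithmetic mean of linear ratios, the use of single spots and the centring on print blocks were chosen after seeing the data, as were both checks of the match to the table. The counts of features past the size rule, 357 higher and 255 lower in clpX, stayed within 1.5 times under median centring, print block centring, the spot of largest size, single usable spots and the arithmetic mean of ratios. The arithmetic mean, without the condition of the same sign, gave 457 higher and 239 lower. A threshold of 1.5-fold gave 706 and 472, one of 3-fold gave 122 and 126, and 2-fold on each array by itself gave 188 and 164. Leaving out 1 array gave 515 to 552 higher and 324 to 385 lower: without array 1 the counts were 552 and 324, and without array 2 they were 515 and 385. limma over both arrays as technical repeats called 138 higher and 134 lower at an adjusted p under 0.05 (416 and 295 unadjusted). In simulated data of this size, with 100 features changed by 1.5 and 100 by 2.0 on the log2 scale, it recovered 46% and 83% of them. It also called 27 of 3991 unchanged features. These 27 were a larger share of all its calls there than the threshold of 0.05 would allow. The 138 and 134 calls are therefore not to be read as held to that error rate. With the second array not turned, 25 and 152 features passed. The agreement of the arrays, r = 0.447, was 0.626 among the 2096 features with the larger mean size. These were chosen by the mean of both arrays, which favours features on which the arrays agree, so a higher r follows from the choice. The number of table values found among the features, 372, was 105 with array 1 inverted in its place and 98 after moving every table value by the same small amount. For the gene lists, 17 of 20 alternatives moved the value by at most 0.33 on the log2 scale. Some of these could not move it. In the thiol redox, chaperone and protease, and iron lists no listed genes counted as neighbours, so counting neighbours once left their medians unchanged. The moves of all 20 were set against 0.45, the SD of an array's deviation from the mean of both over features past the size rule. This SD of single features is wider than the technical error of a median over many genes. The median log2 ratio of the 3 nucleotide genes, 1.68, was 0.13 as a mean and -0.74 when neighbouring list members counted once, since pyrE and pyrD then made 1 value against pbuG. The prophage list's median of -2.01 was -1.54 when neighbours counted once. The causes of the other changes were not tested. Lists could not be recomputed by array or after centring, nor the agreement on named rows or the overlap by identifier, because the value table's rows have no gene names, and the spx transcript was not analysed here. No paired analysis was possible because each strain has 1 preparation.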

Other observations

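The tests of the difference between the arrays and of how the table was selected were chosen after the values were seen. Several neighbouring genes of the authors' deposited table went the same way, listed here by a rule set afterwards: at least 3 adjacent listed genes in 1 direction. Of 22 such runs, 12 held members of the fixed lists. The other 10 were 6 lower and 4 higher in clpX. Among these 10, lower runs included dltB, dltC, dltD and dltE (ratios 0.097 to 0.21), pdhA, pdhB and pdhC of pyruvate dehydrogenase (0.1585 to 0.313), oppA, oppB and oppC of the oligopeptide permease (0.29 to 0.3765), and treP, treA and treR of trehalose use (0.132 to 0.4925). The run mleA, mleN and ansB was at 0.241 to 0.289. Higher runs included yukC, yukD, yukE and adeR (2.689 to 6.6975) and yhfI, lplJ and yhfK (4.6115 to 7.593). Of 88 pairs of adjacent listed genes, 84 had the same direction, where shuffled directions gave a median of 44 and at most 64. Random placement of the 323 genes with a known order gave at most 44 adjacent pairs. One hypothesis is that operons were read as units; its test asked for more same-direction pairs than the 99th percentile of the shuffles, which was 55, and the 84 pairs exceeded it. The gene yjbH, whose product is the adaptor for Spx degradation, had a ratio of 4.85 in that table and was picked after its value was seen.

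The arrays differed from each other after the second was turned. The deviation from their mean had an SD of 0.480 across features, against 0.776 for the mean. Whether this deviation is common to both arrays or each array has its own was not tested. It correlated with r = 0.858 between the 2 spots of a feature, which argues against random spot noise. Print block means explained 0.106 of its variance, which argues against differences between print blocks as the whole cause. Position within a block was not tested. A dye effect could account for the deviation only if the dyes were swapped, because under the dye labels it would follow the strain. A constant scaling factor of each array would shift all its features alike and add nothing to this SD. A dye effect of swapped dyes, the heat steps that the labels name for channel 2, or uneven scaling across features may account for the deviation. These cannot be told apart because 2 arrays confound them.

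Ribosomal protein, motility and PBSX genes sit in long operons, so a region of lower transcripts anywhere on the chromosome might give such lists many lower genes. When each list was shifted along the gene order in all possible steps, as many lower genes were found in at most 0.378% of shifts (the prophage list), 0.165% for motility and none for ribosomal proteins. The bound set beforehand for these lists was under 1%, which the anaerobic list, at 1.20%, would not have met. No shift of the ribosomal list held more than 22 lower genes, against 28 in place. Single shifts of the motility and prophage lists held up to 25 and 21, above their own 22 and 17. For ribosomal protein, motility and prophage genes these values argue against chromosomal clustering as the sole source. They do not exclude it for the motility and prophage lists. Whether the strains differed in growth rate was not tested, and no biological explanation was tested.

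Fewer genes were in the authors' deposited table than features past 2-fold by its formula. Of 457 features at 2 or more, 246 had no counterpart among the table's values, and of 239 at 0.5 or less, 46 had none. These counts are approximate, since features were matched by value only. The matched features, 211 higher and 193 lower, outnumber the 201 and 177 genes named, so some matches were false. The features without a counterpart differed more between the arrays, by a median of 1.20 against 0.485 on the log2 scale for higher features, and 0.897 against 0.521 for lower ones. A rule of 2-fold on each array would be a candidate explanation, for which at most 4 exceptions were allowed, the matches found after moving the table values one way. Of the 108 features uniquely matched to table values above 3, 6 were under 2-fold on 1 array. Moving the values the other way gave 6 matches, which these exceptions do not exceed. Matches of moved values overstate false unique matches, since a value with a true counterpart cannot match another feature alone. With 2 of 114 values unmatched, about 0.111 false matches were expected at the higher of these rates, a criterion set after the result was seen. The 6 lay between 1.79-fold and 1.99-fold on that array, and 5 stayed under 2-fold with spots averaged as linear ratios. This argues against an exact rule of 2-fold on each array, while a somewhat lower limit remains open for the 6. However, 24 higher and 9 lower features past 2-fold on each array had no counterpart. A lower limit alone would not leave these out, and control probes among the features remain open.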
